A study of Mus musculus with 2 samples.

How the data were processed

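Droplet-based single-cell RNA sequencing of mouse liver, dissociated by enzymes and cleaned on a Percoll gradient per the labels, was read in 2 samples of 1 group, WT replicate 1 and WT replicate 2. The deposited table holds raw UMI counts, whole numbers of molecules per gene and cell, and the authors list Cell Ranger 2.1.1, Seurat 3.1 and the assembly GRCm38 in their processing notes. What each of these tools did to the cells of the table, and which cells were removed before, is not stated. All cells stand in 1 table of 22508 genes and 9703 cells, and the number at the end of each barcode (1 or 2) was read as the replicate number. 5 barcodes occur with both endings and were treated as separate cells. Of the gene symbols 22490 (99.92%) are in GENCODE vM21, which gave the coordinates.

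The depth per sample was 40645060 UMIs in 7362 cells (503 to 66125 per cell) for replicate 1 and 11867207 UMIs in 2341 cells (1263 to 13401 per cell) for replicate 2. Cells with at least 200 genes and at most 20% mitochondrial UMIs were used. This removed 597 cells (8.11%) of replicate 1, where the highest mitochondrial share was 97.5%, and 0 of replicate 2, where it was 6.26%. Doublets were called by the Scrublet method in scanpy, per sample. It called 9 of 6765 cells (0.133%) in replicate 1 and 16 of 2341 (0.683%) in replicate 2. Such a low number in a library of that size may mean that the calling has not worked in replicate 1. Doublets may thus remain there, and removal of the highest 5% of scores was added as an alternative. Free RNA was not subtracted, since empty droplets were not analysed here.

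UMIs were scaled to 10000 per cell and log-transformed. Clusters were made on both samples together, without batch correction, from 2000 variable genes, 30 principal components of values clipped at 10, 15 neighbours and the Leiden method at resolution 1. Genes of the fixed lists, check genes and landmarks were left out of the variable genes unless they were also cell type markers, so list genes did not define the clusters. A cluster received the class with most markers among its 10 leading genes and among markers seen in at least 10% of its cells at over 2-fold the other cells. At least 3 such markers were needed. A cluster stayed unnamed if its leading genes held more markers of another class, if at least 3 of them were cell cycle genes, or if none was a marker and 3 times its median UMI number was still below that of its sample. These details of the rule were set after the clusters had been seen. The unnamed clusters held 1222 cells (18.1% of replicate 1) and entered no comparison. Classes are called "-like", since naming rests on markers alone.

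The plan was a quasi-likelihood test on counts summed per sample and class, with the sample as a block, for classes with at least 20 cells in both samples. No class met this, since none had 20 cells in both samples. The rule written beforehand for a table that counts as 1 sample was used instead: no test, values with exact intervals of 95% that cover counting error only, and a gene named if it differed at least 2-fold with at least 50 UMIs over the sides compared. Sums were scaled to CPM. Intervals of levels are Poisson intervals, intervals of ratios between ranges are exact binomial intervals conditional on the sum, and shares of cells have exact binomial intervals. For a share of 0 the limit given is 3 cells of the total, and the exact interval for 0 of 2325 cells reaches 0.159%. A value of 0 was set to 3 counts for a ratio, and no ratio was formed where both sides had at most 3.

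For class comparisons each of 15 classes with at least 20 cells was summed in its own library, from 65847 UMIs in neutrophil-like to 12935181 in sinusoidal endothelial-like cells, and the stellate-like or sinusoidal endothelial-like class was set against the mean CPM of the 14 others. The 13 fixed lists, from collagens to G protein-coupled receptors, were written before the counts were read, and genes that serve as markers were dropped from them. The median log2 fold change of a list was placed among 10000 random lists of genes matched on expression. From each list up to 4 genes with the largest change were named, plus genes at least 2-fold above every other named class, and the text and figures give a selection of these. The latter genes were also read in the unnamed clusters, which was added after the data were seen.

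For the central to portal axis each cell had a score, the mean z value of 4 central landmarks minus that of 4 portal landmarks, and the cells were split into 3 equal ranges of which the outer ones were compared. Landmarks were chosen from general knowledge before the counts were read and took no part in the gene counts, and a landmark's own fold is given only from a score made without it. Genes named came from the 10 with the largest change on each side, leaving out mitochondrial, ribosomal protein and model genes, from up to 4 genes per list, and from the check genes Rspo3, Wnt2, Tagln, Gper1, Lrat and Lhx2. After the result was seen, genes with at least 20% of their UMIs in 1 cell were also listed apart.

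The method was tested on simulated cells with 200 changed genes. Their counts had Poisson spread around each cell's depth times the gene's mean, without clusters or cells of other types. The landmarks were given a 10-fold change. Of those with a 10-fold change from end to end, 100 of 100 passed the rule in both classes. Of those with a 3-fold change, 18 and 22 of 100 passed in stellate-like and endothelial cells, and of the unchanged genes 9 of 9491 and 11 of 9410. Real cells vary beyond this setting, so the numbers of unchanged genes that passed are no error rate for them.

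Alternatives planned beforehand were median-ratio size factors, no floor on UMIs, the highest other class in place of the mean, doublets kept, at least 500 genes with at most 10% mitochondrial UMIs, resolutions 0.5 and 2, all variable genes, the outer of 4 ranges of the score, each landmark left out, cells thinned to 2000 UMIs and 20 draws of random landmarks. Added after the data were seen were the 11 stellate-like cells of replicate 1, removal of high doublet scores, the Rasd1 cluster left out, the 2 stellate-like clusters in place of the score, genes held by 1 cell left out, and both resolutions for the score comparisons. Python 3.11.15 was used with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9.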

Results

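Single cells of healthy mouse liver were profiled by droplet-based 3' RNA sequencing in 2 samples of 1 group, WT replicate 1 and WT replicate 2, from 8-week-old C57BL/6 mice. The table held raw UMI counts of 22508 genes in 9703 cells. WT replicate 1 had 7362 cells and 40645060 UMIs, and WT replicate 2 had 2341 cells and 11867207 UMIs. After the cell filter and removal of called doublets, 6756 cells of replicate 1 (median 4722.5 UMIs, 2130 genes) and 2325 cells of replicate 2 (median 5002 UMIs, 2236 genes) were kept. The lowest UMI number of a cell was 503 in replicate 1 and 1263 in replicate 2. The labels do not say that the samples came from separate animals.

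The first question was which cell classes each sample held. Stellate-like cells, with Lrat, Dcn, Reln and Colec11 among their markers, were 2319 of 2325 cells of replicate 2 (99.7%, 95% interval 99.4 to 99.9) and 11 of 6756 cells of replicate 1 (0.163%, 0.0813 to 0.291). In replicate 1 the largest class was sinusoidal endothelial-like, with Stab2, Clec4g and Kdr as markers, at 2524 cells (37.4%, 36.2 to 38.5). Kupffer-like cells with Clec4f, Vsig4 and Timd4 followed at 1664 cells (24.6%, 23.6 to 25.7). Hepatocyte-like cells made up 231 (3.42%), T-like cells, which also carried Gzma and Nkg7, 225 (3.33%), mesothelial-like cells 178 (2.63%) and vascular endothelial-like cells 165 (2.44%). Monocyte-like cells, with Mgl2, Ccl8 and the dendritic marker Xcr1 also among their leading genes, numbered 139 (2.06%). At clustering resolution 2, 16 cells were named conventional dendritic-like. Portal fibroblast-like cells numbered 121 (1.79%) and cholangiocyte-like cells 114 (1.69%). Of B, plasmacytoid dendritic, lymphatic endothelial, neutrophil and smooth muscle-like cells there were 43, 40, 31, 27 and 21. Replicate 2 held 6 smooth muscle-like cells (0.258%) and 0 of 2325 cells of any other named class, which allows a share of up to 0.129% for each.

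3 clusters of replicate 1, 1222 cells (18.1%), met no naming rule. They were led by Wnt9b, Lhx6, Selp and Vwf (336 cells, 4.97%), by the cell cycle genes Top2a, Ube2c and Mki67 (143 cells, 2.12%), and by Naip1, Hdac9 and Il10 (743 cells, 11.0%, median 1394 UMIs). The unnamed share of replicate 1 was 6.78% at clustering resolution 0.5, 12.0% at resolution 2, 12.3% with all variable genes, 6.84% with doublets kept and 7.15% under the stricter filter, where the stellate-like share was 0.0980% (6 cells). The hepatocyte-like share was 1.24% at clustering resolution 2 and 1.81% under the stricter filter, and the vascular endothelial-like share 5.27% with all variable genes and 3.73% at resolution 2. Shares were counted in the cells that the table held, and the lowest and median UMI numbers given above differed between samples. A class found in 1 library only may be that library rather than a property of the liver. No test between groups was run, as there was 1 group.

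**Figure D1:**
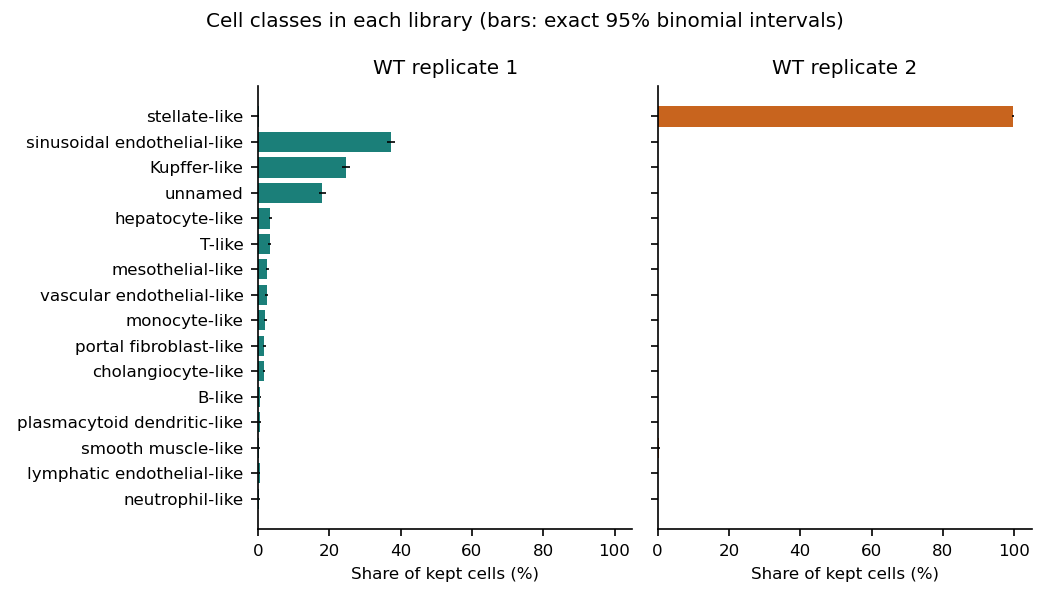
Share of cells (%) in each named class and in unnamed clusters, by sample, with exact 95% binomial intervals. Stellate-like cells made up 99.7% of replicate 2 and 0.163% of replicate 1.

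The second question was which matrix, signalling and receptor genes marked the stellate-like cells of replicate 2 against the 14 other classes, all of replicate 1. The basement membrane chain Lama1 reached 149 CPM (UMIs scaled to a sum of 1000000; 142 to 156, counting error only, 2319 cells), against at most 0.709 CPM, 1 UMI, in any other class. Bmp10 and Gdf2, circulating ligands of the endothelial receptor Acvrl1, reached 239 (230 to 248) and 864 CPM (847 to 881). The highest other classes held 1.17 CPM of Bmp10, 1 UMI in portal fibroblast-like cells, and 37.5 CPM of Gdf2 in mesothelial-like cells. Rspo3, which strengthens Wnt signals through Lgr receptors, stood at 1260 CPM (1239 to 1280), 21.9-fold above portal fibroblast-like cells, but below the 2293 CPM (2224 to 2363) of the unnamed cluster of 336 cells led by Wnt9b, which was not among the 14 classes. Cxcl12, the ligand of Cxcr4, stood at 5040 CPM (4999 to 5080), 5.53-fold above the same class.

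Against the mean of the other classes, 117 genes of the fixed lists were at least 2-fold higher in stellate-like cells and 141 at least 2-fold lower. Against the highest other class per gene, in place of the mean, 26 were higher and 271 lower. Of the 26, all but Rspo3 were also at least 2-fold above each unnamed cluster. Beside the genes above, these 26 included Hhip, which binds hedgehog ligands, at 528 CPM (515 to 541), and Bmp5 at 649 (634 to 664). The lectin-pathway genes Colec10 (61.3-fold over the highest other class) and Masp1 (7.63-fold), the peptide receptor Vipr1 (24.4-fold), the angiotensin receptor Agtr1a (11.2-fold) and the endothelin receptor Ednra (4.24-fold) were also among them. So were Fgfr2 (6.36-fold), Tgfbi (5.41-fold), Prelp (3.57-fold), Col14a1 (2.42-fold), Bgn (2.29-fold) and Aldh1a3 (2.13-fold).

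By list, collagens had 8 of 20 genes higher, 8 lower and 4 within 2-fold. Col14a1 was 18.3-fold above the mean, while Col1a1 at 76.3 CPM was far below the 1835 CPM of portal fibroblast-like cells. Matrix glycoproteins and proteoglycans had 14 of 37 higher and 11 lower, with Prelp at 2001 CPM and Mgp at 6.997 CPM as examples on either side. Matrix crosslinking and turnover had 13 of 29 higher and 8 lower. Each of these 3 lists had a median log2 fold change above 0 (0.50, 0.55 and 0.53) and lay at or above percentile 99.8 of random lists matched on expression. G protein-coupled receptors had 12 of 28 higher and 10 lower (median 0.74, percentile 100), with Vipr1, Ramp1 at 1069 CPM and Adra2b at 132 CPM among the higher ones. TGF-beta and BMP signalling had 12 higher, 12 lower and 12 within 2-fold, and Notch and hedgehog signalling 5 higher and 6 lower of 17. Guidance and neural genes split into 12 higher and 12 lower of 29, with Robo2 (226 CPM) on the higher side. Their median log2 fold change was -0.81, at percentile 1.17 of random lists.

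Lower members outnumbered higher ones among growth factors and receptors (21 against 8 of 39), retinoid and lipid storage (11 against 5 of 20), complement and coagulation (11 against 5 of 22) and Wnt signalling (11 against 6 of 28). The medians of these lists lay at percentiles 0, 0.09, 0.08 and 2.98 of random lists, in that order. Igfbp5, which binds insulin-like growth factors, had 7 UMIs in all stellate-like cells (0.597 CPM, 0.240 to 1.23) and 11326 CPM in mesothelial-like cells. Igfbp6, Ptn, Rspo1 and Sfrp1 had 0 UMIs, which allows up to 0.315 CPM. Their means over the other classes were 573, 77.2, 58.4 and 55.4 CPM. In the retinoid list the plasma retinol carrier Rbp4 stood at 4.86 CPM against 4639 CPM in hepatocyte-like cells, and Aldh1a3, which makes retinoic acid, at 62.5 CPM (58.1 to 67.2). Cytokines, chemokines and adhesion genes had 8 of 32 higher and 11 lower, and contractile and activation genes 9 higher and 9 lower of 27. The smooth-muscle gene Tagln stood at 162 CPM in stellate-like and 10381 CPM in smooth muscle-like cells.

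**Figure D2:**
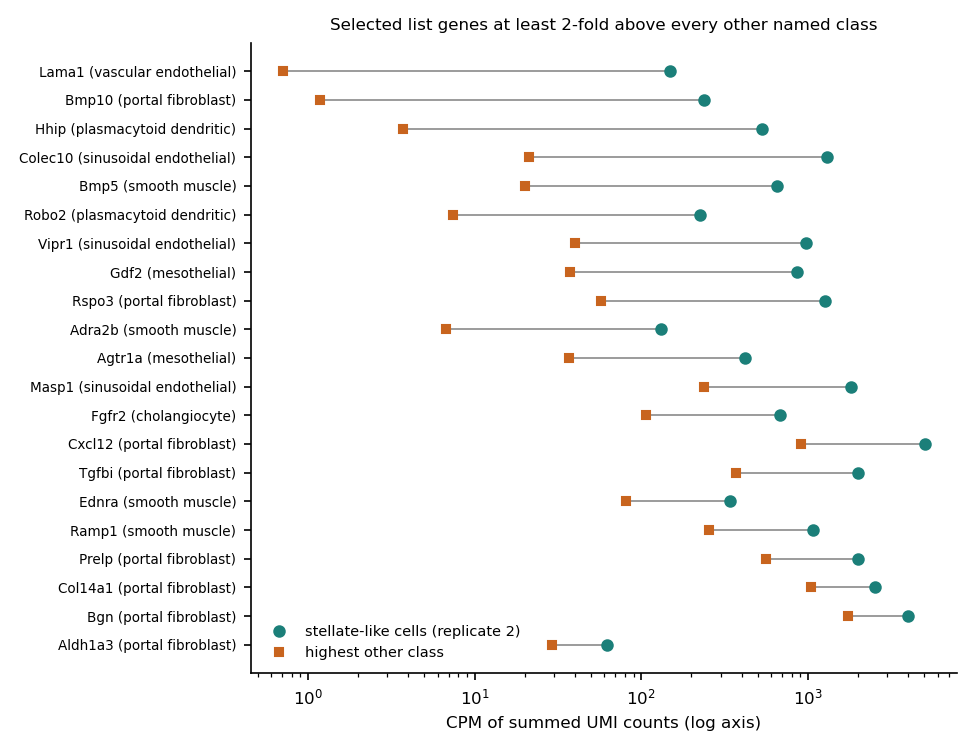
Selected list genes at least 2-fold higher in stellate-like cells than in every other named class, as CPM on a log axis. Circles are the stellate-like cells and squares the highest other class, which is named beside each gene, with Lama1 at 149 against 0.709 CPM and Aldh1a3 at 62.5 against 29.3 CPM.

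No test was run on this comparison, because no class had 20 cells in both samples and every difference of the stellate-like class was also a difference between libraries. As an alternative chosen after seeing the data, the 11 stellate-like cells of replicate 1 (34370 UMIs) were set against the same classes within their own library. Of 79 higher list genes with enough expected counts 52 were again at least 2-fold higher, and of 49 lower ones 28 were again at least 2-fold lower. Notch3, 3.75 CPM against a mean of 32.0 CPM, turned direction at clustering resolutions 0.5 and 2, where 9 smooth muscle-like cells joined the stellate-like class. The smooth muscle-like class, otherwise at 396 CPM of Notch3, then held 18 cells, fewer than 20, and was out of the comparison. Which of these changes turned the gene was not told apart.

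The same lists were then read in the sinusoidal endothelial-like cells against the 14 other classes, of which all but the stellate-like class came from the same library. Bmp2, a ligand of BMP receptors, stood at 2599 CPM (2572 to 2627, 2524 cells), 3.28-fold above the highest other class, B-like cells with 138 UMIs. B-like cells were also the highest other class for Wnt2, Nrp1, Tfpi and Cd55. They held the endothelial marker Clec4g at 821 CPM, against 2775 CPM in sinusoidal endothelial-like cells. Whether endothelial RNA in B-like cells lowered these folds was not tested. Cyp26b1, which breaks down retinoic acid, stood at 1425 CPM (1404 to 1446), 4.45-fold above vascular endothelial-like cells. Bmp6 reached 209 CPM (201 to 217), Wnt2 289 (280 to 299) and the coagulation factor gene F8 913 (897 to 930). Against the mean of the other classes 74 list genes were at least 2-fold higher and 225 at least 2-fold lower. Against the highest other class 12 remained higher: the 5 above with Nrp1, P2ry1, Lifr, Tfpi, Adgrl4, Col13a1 and Cd55. None of the 12 was 2-fold above the unnamed cluster of 336 cells, which had 739 CPM of Wnt2, 2020 of Bmp2 and 1592 of Cyp26b1.

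Among collagens 16 of 20 were lower and 3 higher, and Col1a1 had 7 UMIs (0.541 CPM). Of matrix glycoproteins 26 of 37 were lower, with Ogn at 0.696 CPM and Sparcl1 at the same level, and 4 were higher. TGF-beta and BMP signalling had 11 of 36 higher, with Bmp2 and Bmp6, and 20 lower, with Bmp4 at 3 UMIs. Wnt signalling had 6 of 28 higher, with Wnt2 and the receptor Fzd4 at 307 CPM, and 18 lower. Cytokines, chemokines and adhesion genes had 8 of 32 higher and 19 lower. Guidance genes had 6 of 29 higher and 20 lower, and complement and coagulation 6 of 22 higher, with F8, Tfpi and Cd55, and 13 lower. All 13 lists had a negative median log2 fold change, from -1.33 for cytokines to -5.17 for collagens. No test was run, as no class had 20 cells in both samples.

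The third question, raised by the title of the series, was which genes differed among stellate-like cells along an axis from central-vein to portal landmarks. Each of the 2319 cells of replicate 2 was scored by Adamtsl2, Loxl1, Podn and Spon2 (central) against Ngfr, Itgb3, Igfbp3 and Il34 (portal), and the score was split into 3 ranges of 773 cells. These are parts of a score and not cell types, and 347 cells lay within 0.1 of a boundary. Tissue position was not measured. With a landmark left out of the score, its own difference stayed: Spon2, a secreted matrix protein, was 6.61-fold higher in the central range (4.85 to 9.20), Podn 4.37-fold (3.79 to 5.06) and Loxl1 3.77-fold (2.92 to 4.90). Ngfr, a neurotrophin receptor, was 4.31-fold higher in the portal range (3.67 to 5.09), Igfbp3 3.37-fold and Il34, a ligand of Csf1r, 2.76-fold (2.37 to 3.23).

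Of 9704 genes with enough UMIs, 110 were at least 2-fold higher in the central range and 99 in the portal range. The central side was led by F3, which starts coagulation as tissue factor, at 15.1-fold (5.59 to 57.4; 57 against 4 UMIs). Colec12, a scavenger receptor, followed at 9.47-fold (5.33 to 18.3), then Grid1 at 7.96-fold (3.79 to 19.3) and the methyltransferase Inmt at 7.84-fold (5.77 to 10.9). Crispld2 (6.55-fold), the thyroid hormone receptor Thrb (6.37-fold), Fam180a (6.19-fold), the chemokine scavenger Ackr4 (6.07-fold), the semaphorin receptor Plxna4 (6.00-fold) and the adhesion gene Alcam (5.77-fold, 4.86 to 6.90) completed the leading 10. The portal side was led by the potassium channel Kcnk3, 32.5-fold higher (8.66 to 274; 17.1 against 0.527 CPM, 2 UMIs) and the smooth-muscle myosin Myh11, 28.3-fold (9.37 to 140; 3 UMIs in the central range). Tmem178 was 21.4-fold higher and the latrophilin Adgrl3 13.4-fold. Trarg1 (10.7-fold), Lsamp (9.11-fold), Ahnak2 (8.79-fold), vitronectin Vtn (8.48-fold) and Rgs4, which shortens G protein signals (8.41-fold, 6.74 to 10.6; 197 against 23.4 CPM), were also among the leading genes of that side.

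Of the check genes, Rspo3 was 1.87-fold higher in the central range (1.79 to 1.95; 1568 against 840 CPM) and the stellate transcription factor Lhx2 1.38-fold (1.29 to 1.49). Tagln was 1.94-fold higher in the portal range (1.73 to 2.17) and Lrat, which esterifies retinol, 1.20-fold (1.15 to 1.25). Wnt2 had 1.11-fold more in the central range (0.724 to 1.70; 12.6 against 11.4 CPM, beside 289 CPM in sinusoidal endothelial-like cells), and Gper1 had 0 UMIs in both ranges.

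Among 15 collagens 2 were higher in the central range, Col1a1 (2.60-fold, 2.18 to 3.11) and Col27a1 (2.25-fold), and 13 stayed within 2-fold. Matrix glycoproteins split, with Lum (2.15-fold) and Ogn (2.87-fold) central, and Fn1 (3.55-fold, 3.21 to 3.93; 457 against 129 CPM), Nid2 (2.52-fold), Vtn and Lama1 (2.06-fold) portal, out of 30. In crosslinking and turnover the proteases Htra3 (5.33-fold) and Adamts5 (3.22-fold) were central and Htra1 (2.33-fold) portal, and 19 of 22 stayed within. With the 2 stellate-like clusters in place of the score, an alternative added after seeing the data, 19 of 31 list genes stayed past 2-fold, 30 kept their direction and Htra1 turned. Between the clusters Ackr4 was 1.96-fold, Vegfa 1.97-fold, Col27a1 1.80-fold, Fgfr1 1.57-fold, Epha4 1.55-fold, Lum 1.52-fold, Dkk3 1.40-fold and Aldh1a3 1.29-fold central. Nid2 was 1.87-fold, Lama1 1.75-fold and Hey2 1.04-fold portal, while Tagln was 1.06-fold central (0.965 to 1.17). Of those still past 2-fold, F3 fell to 6.80-fold, Procr to 4.53-fold, Vtn to 3.93-fold, Htra3 to 3.11-fold, Colec12 to 2.90-fold, Heyl to 2.80-fold and Fn1 to 2.01-fold. All 4 growth factor genes past 2-fold were central: Igf1 (3.75-fold, 2.45 to 5.93), Vegfa (3.45-fold), Mdk (3.34-fold) and Fgfr1 (2.27-fold). Both Wnt genes past 2-fold, Dkk3 (4.34-fold; 46.3 against 10.7 CPM) and the receptor Fzd7 (2.63-fold), were central too. Both lists had medians at percentile 100 of matched random lists (log2 0.24 and 0.42).

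On the portal side were the Notch targets Heyl (5.14-fold, 3.71 to 7.26) and Hey2 (2.07-fold), the monocyte attractant Ccl2 (3.93-fold, 3.63 to 4.27; 742 against 189 CPM) and Cxcl10 (2.06-fold). Cytokines, chemokines and adhesion genes had the lowest median of all lists (log2 -0.36, percentile 0), with Ackr4 as their only central gene. Contractile and activation genes had 24 of 24 within 2-fold and a median log2 of -0.20, percentile 0. In complement and coagulation F3 and Colec12 were central, and the protein C receptor Procr (7.40-fold, 3.36 to 19.3) and Cfb (2.56-fold) portal. The lysophosphatidic acid receptor Lpar1 (2.86-fold) was central and the sphingosine phosphate receptor S1pr3 (2.21-fold) portal. Aldh1a3 (2.01-fold), Plxna4 and Epha4 (2.36-fold) were central, and all 28 TGF-beta and BMP genes stayed within 2-fold.

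**Figure D3:**
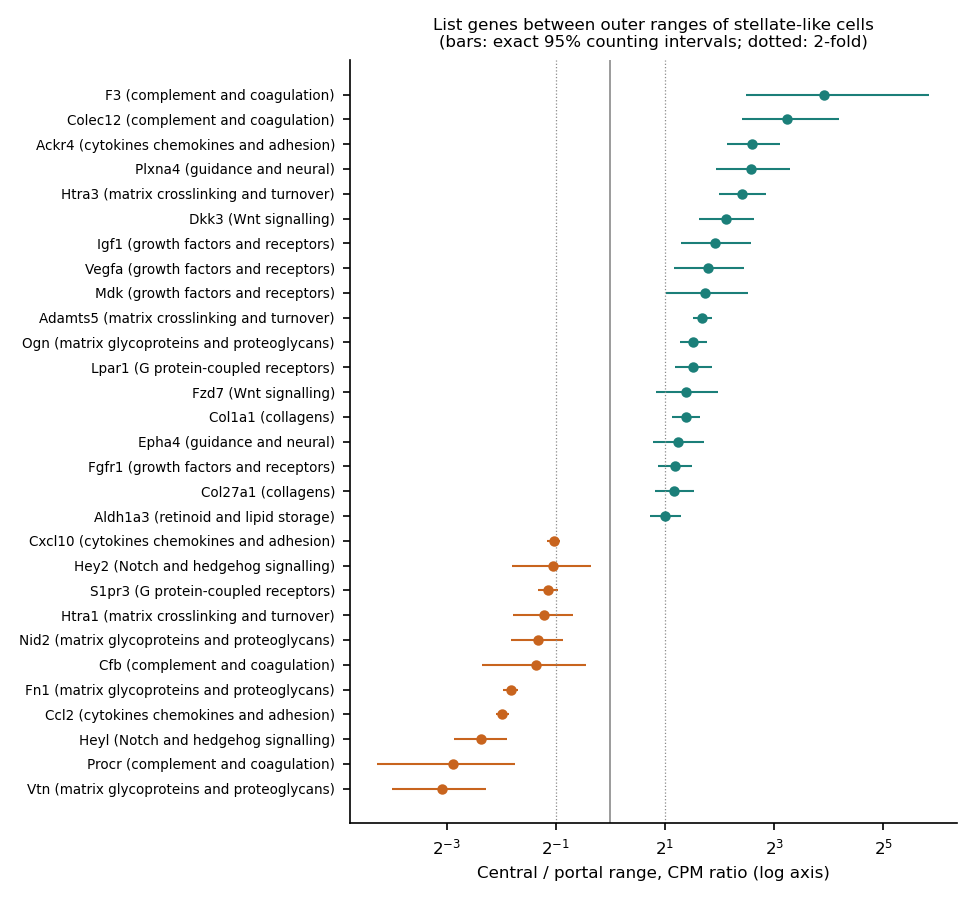
CPM ratio of the central to the portal range of stellate-like cells on a log axis, for up to 4 genes per list past 2-fold, with 95% counting intervals. Points right of 1 were higher in the central range, led by F3 (15.1-fold), and points left of 1 in the portal range, led by Vtn (8.48-fold).

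The central range held 3798137 UMIs (median 4819 per cell) and the portal range 4031248 (median 5254). Of the central range 34.9% and of the portal range 85.9% were cells of the stellate-like cluster with Ngfr and Il34 among its leading genes. Of the smooth muscle markers, Mustn1 stood at 573 CPM in the central and 435 CPM in the portal range, and Myh11 at 0.790 and 22.3 CPM, against 4046 CPM in smooth muscle-like cells. Acta2 stood at 4.74 and 2.48 CPM, and Cnn1, Actg2, Pln and Rcan2 had 0 UMIs in both ranges. Of the portal fibroblast markers, Eln stood at 39.0 and 16.9 CPM. Dissociation stress genes summed to 16660 and 18589 CPM. Landmarks drawn at random with matched expression gave a median of 17.5 genes past 2-fold over 20 draws (at most 25). In simulated cells 18 of 100 genes with a 3-fold and 100 of 100 with a 10-fold change from end to end passed the rule, so a gene within 2-fold was not shown to be level. With cells thinned to 2000 UMIs and the score remade, 57 central and 69 portal genes passed, 39 and 42 of them the same as at full depth. Without the floor of 50 UMIs per gene 857 central and 653 portal genes passed 2-fold. No test was run, since all the cells came from 1 library, and the intervals leave out differences between animals.

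The same axis was read in 2524 sinusoidal endothelial-like cells of replicate 1 by Kit, Thbd, Cdh13 and Wnt9b (central) and Efnb2, Dll4, Ltbp4 and Msr1 (portal), with 841 cells in either outer range and 404 within 0.1 of a boundary. Left out of the score, Wnt9b was 11.1-fold higher in the central range (5.13 to 28.5), Cdh13 6.53-fold (5.44 to 7.89) and Kit, the stem cell factor receptor, 3.93-fold (3.54 to 4.38). The scavenger receptor Msr1 was 3.81-fold higher in the portal range (3.49 to 4.17), the ephrin Efnb2 3.58-fold (3.15 to 4.08) and the Notch ligand Dll4 2.56-fold (2.24 to 2.93). Of the check genes Rspo3 was 16.7-fold central (9.30 to 32.8; 44.4 against 2.66 CPM) and Wnt2 4.97-fold central (4.49 to 5.50; 517 against 104 CPM). Tagln, Lrat and Lhx2 had intervals that included 1, and Gper1 had 0 UMIs.

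Of 9556 genes 87 were at least 2-fold higher in the central range and 111 in the portal range. Of the 10 leading central genes 9 had at least 20% of their UMIs in 1 cell: the hemoglobin genes Hbb-bt and Hba-a2, the mast cell genes Cma1, Mcpt4, Tpsb2 and Cpa3, and Ccl3, Ccl4 and Ptgs2. Cma1, at 55.7 CPM, was read in 1 cell only. Without such genes 73 central and 111 portal genes were left. The leading central genes with under 20% of their UMIs in any 1 cell were the transcription factor Lhx6 (61.1-fold, 10.5 to 2456), Rspo3, the receptor-modifying gene Ramp3 (12.0-fold, 4.83 to 38.4) and the clock-output factor Hlf (10.2-fold). The semaphorin Sema3d (5.24-fold), Wnt2 and the neurotrophin Ntf3 (4.64-fold) were also among these. Lhx6 was read in 42 cells of the outer ranges, with 1 UMI in the portal range, and Rspo3 in 83 cells. Lhx6 and the central landmarks Wnt9b and Cdh13 were also leading genes of the unnamed cluster of 336 cells, where Rspo3 stood at 2293 CPM. Whether cells or RNA of that cluster lay in the central range was not tested. The portal side was led by the adhesion receptor Adgrg6 (27.0-fold, 12.9 to 68.0; 46.6 against 1.73 CPM), Slc45a4 (26.6-fold, 13.8 to 58.8) and the lymphangiogenic factor Vegfc (16.7-fold, 7.89 to 42.4). Esm1 (14.3-fold), the endothelin receptor Ednrb (9.41-fold), Gprc5c (8.30-fold), Tox2 (7.06-fold), Galnt15 (6.56-fold), the guanylate cyclase subunit Gucy1b1 (6.14-fold) and Mecom (4.97-fold) followed.

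All 3 Wnt list genes past 2-fold, Rspo3, Wnt2 and Dkk3 (3.53-fold, 2.73 to 4.61), were central, out of 11 (median log2 0.27, percentile 99.96). The 3 matrix glycoproteins past 2-fold, Ntn4 (3.82-fold, 3.52 to 4.14), Fbn1 (2.91-fold) and Lama4 (2.22-fold), were portal, as was Htra1 (3.56-fold). Growth factors split, with Gas6 (2.43-fold), Pdgfa (2.59-fold) and Fgf1 (2.29-fold) central and Vegfc, Angpt2 (3.72-fold), Ccn1 (2.68-fold) and Ccn2 (2.05-fold) portal. Cytokines, chemokines and adhesion genes gave 6 central genes, among them Lgals1 (3.87-fold, 3.50 to 4.29), Ackr4 (2.90-fold) and Ptgs1 (2.49-fold), and 3 portal genes, Il33 (2.17-fold), Cxcl9 (2.04-fold) and Cxcl1 (2.01-fold). The fatty acid carrier Fabp4 was central (2.47-fold) and the fatty acid receptor Cd36 portal (2.09-fold). Tgfbi (2.55-fold) was central and Bmper (2.15-fold) portal, Ramp3 was central and Ackr1 (2.35-fold) portal, and Efnb1 (3.14-fold) was portal. All 6 collagens, 7 Notch and 16 complement genes stayed within 2-fold, and the Notch list had a median log2 of -0.48 (percentile 0.0400).

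**Figure D4:**
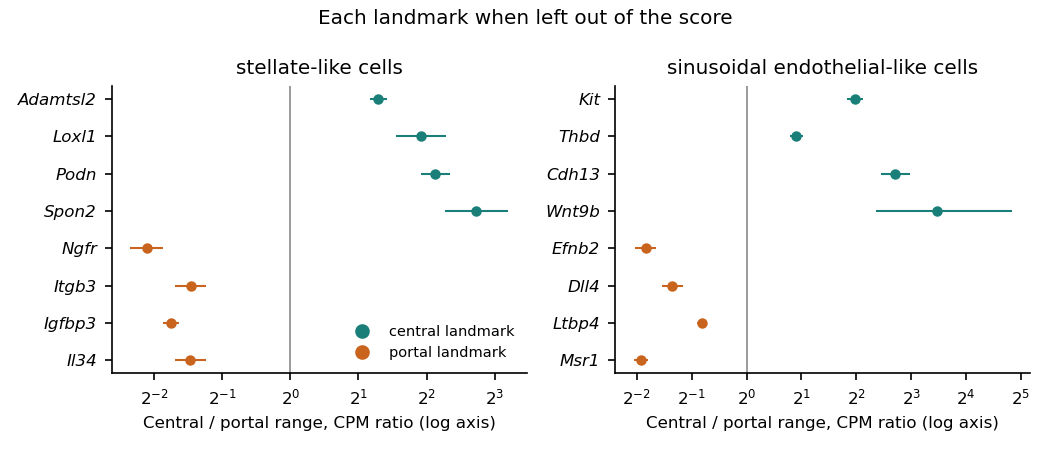
CPM ratio of the central to the portal range for each landmark, with a score made without it, on a log axis with 95% counting intervals, for stellate-like and sinusoidal endothelial-like cells. Every landmark kept its side, from Ltbp4 at 1.76-fold to Wnt9b at 11.1-fold.

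The outer endothelial ranges held 4057741 and 4506420 UMIs (median 4660 and 4907 per cell). Beside the axis, erythroid markers summed to 512 CPM in the central and 37.1 CPM in the portal range, basophil or mast markers to 40.9 and 0 CPM, and stress genes to 8045 and 11502 CPM. Portal fibroblast markers, mostly Cd34, summed to 12.3 and 44.6 CPM (0.276-fold, 0.198 to 0.378), and megakaryocyte or platelet markers to 24.6 and 12.0 CPM (2.06-fold, 1.46 to 2.92). Cd34 is also a marker of the vascular endothelial list, which summed to 938 and 1019 CPM (0.920-fold, 0.881 to 0.961). Of the central range 50.8% and of the portal range 31.5% were cells of a cluster with a median of 2912 UMIs, and 17.2% and 35.7% were of the cluster led by Rasd1. Random landmarks gave a median of 25 genes past 2-fold over 20 draws (at most 87). With cells thinned to 2000 UMIs and the score remade, 52 central and 44 portal genes passed, 36 and 30 of them the same as at full depth. Without the floor on UMIs per gene 688 and 671 passed, and without the cluster led by Rasd1 the portal side fell to 73. Il6 (4.30-fold central) and Ccl4 turned direction when doublets were kept, under the stricter filter, at resolution 2 and without that cluster. In simulated cells 22 of 100 genes with a 3-fold change from end to end passed the rule. No test was run, since all cells came from 1 library.

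**Figure D5:**
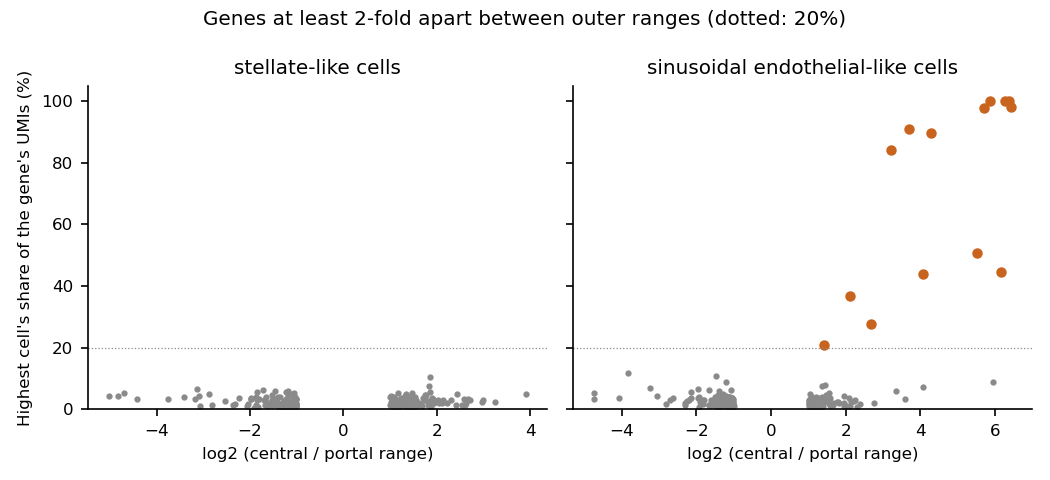
Share of a gene's UMIs held by its highest cell (%) against its log2 ratio of the central to the portal range, for genes past 2-fold in either cell class. 14 endothelial genes, all central, lay at or above 20%, and the highest stellate-like gene stood at 10.5%.

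The last question was whether the same genes followed both axes. Across 8527 genes with enough UMIs in both classes the log2 ratios had a Spearman correlation of 0.0497 and a Pearson correlation of 0.0885. Of these genes 32 were central and 44 portal past 2-fold in stellate-like cells, and 49 and 70 in endothelial cells. Central in both were Dkk3, Cgnl1 and Ackr4, against 0.184 genes if the axes were independent, and Dkk3 and Ackr4 were within 2-fold between the stellate-like clusters. Portal in both were 7 genes, Fam241a, Clca3a1, AW011738, Steap4, Hilpda, Htra1 and Serpina3g, against 0.361, and Htra1 turned direction between the stellate-like clusters. Opposite directions were found for 1 gene each way, against 0.263 and 0.253. The stellate-like and endothelial cells came from different libraries, and no test was run.

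On the mouse assembly GRCm38 with the GENCODE vM21 annotation, Rspo3 lies on chromosome 10 at 29452416 to 29535867, F3 on chromosome 3 at 121723537 to 121735048 and Kcnk3 on chromosome 5 at 30588170 to 30625271. Spon2 lies on chromosome 5 at 33198184 to 33218455, Ngfr on chromosome 11 at 95568818 to 95587735 and Lama1 on chromosome 17 at 67697259 to 67822647. Wnt2 lies on chromosome 6 at 17988940 to 18030585 and Adgrg6 on chromosome 10 at 14402583 to 14545659.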

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

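Of the tests below, those on each marker set taken alone, on the gene number floor, on removal of fibroblast and muscle RNA and on genes held by single cells were chosen only after the result was seen. The others were written down before.

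Some cells stayed outside the comparisons. A cluster of 336 cells of replicate 1 was led by Wnt9b, Lhx6, Selp and Vwf, a cluster of 143 cells by Top2a and other cell cycle genes, and a cluster of 743 cells with few UMIs by Naip1. Replicate 1 also held 11 stellate-like cells, apart from the 2319 of the other library, and 597 cells with more than 20% mitochondrial UMIs.

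One library held almost only stellate-like cells and the other almost none. If cells of other types had been in the second suspension and had been left out of the table after sequencing, their free RNA could have stayed behind in the stellate-like cells. The summed markers of sinusoidal endothelial and Kupffer cells stood at 0.839 times (0.820 to 0.858) their level in 960 cells of replicate 1, with endothelial, Kupffer-like, monocyte-like and unnamed cells left out. This sum decides nothing, as its parts moved apart. Endothelial markers stood at 1.36 times (1.33 to 1.40), 1406 against 1031 CPM. This ratio decides nothing either, as the replicate 1 cells pooled classes with unlike levels. Clec4g stood at 34.2 CPM in cholangiocyte-like, 377 in T-like and 821 in B-like cells, against 244 in stellate-like cells. Kupffer markers stood at 0.125 times (0.117 to 0.133), with 759 CPM in replicate 1. This ratio cannot decide about removal of Kupffer cells, as the same pooled classes differed in these markers too. Clec4f stood at 20.1 CPM in smooth muscle-like and 293 in T-like cells, against 29.8 in stellate-like cells. A different floor on genes per cell as the cause does not go with the data, since only 15.9% of the cells of replicate 1 lay under the lowest gene number of replicate 2. Each of the 9 endothelial markers was read in 18.2% to 57.8% of the stellate-like cells, at a summed 6.77% of the level in endothelial-like cells. Such a thin spread, read only after the data were seen, argues against doublets as the whole source. Whether the endothelial RNA came from removed cells or from endothelial cells lost before capture stays open, and no biological explanation was tested, as there was 1 group.

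Genes differed between the outer ranges of the stellate-like score. Depth is argued against as the whole cause by thinning to 2000 UMIs, after which the median log2 fold change of these genes was 0.900 of that at full depth. Dissociation stress genes moved by a median of 0.159 times the change of these genes. That ratio cannot decide about stress, as these genes were picked for passing 2-fold and the stress genes were not. Summed stress genes stood at 0.896 times (0.887 to 0.906) their portal level in the central range. Summed markers of portal fibroblasts and of smooth muscle cells differed between the ranges by at most 0.568% of the level in those classes, which decides nothing about admixture, as stellate-like cells express Mustn1 themselves (500 CPM against 1745 in smooth muscle-like cells). RNA of these 2 classes, at the upper limit allowed by markers scarcely read in stellate-like cells, was therefore taken off the higher side, and 99.5% of the genes past 2-fold stayed there, with Efhd2 going from 2.01-fold to 1.98-fold and Myh11 from 28.3-fold to 20.2-fold, which argues against such RNA as the whole cause. Tissue position was not measured, and no biological explanation was tested.

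Genes differed between the outer ranges of the endothelial score too. Thinning left 0.872 of the median log2 fold change, so depth does not account for the difference as a whole. Stress genes moved by 0.339 times the change of the genes past 2-fold. This ratio cannot decide about stress, as only the genes past 2-fold were picked for their change. Summed stress genes stood at 0.699 times (0.690 to 0.709) their portal level in the central range. Of the genes past 2-fold 7.07% had at least 20% of their UMIs in 1 cell, which argues against single cells as the source of the whole set. For the 10 leading central genes the same explanation fits, since 9 had at least 20% of their UMIs in 1 cell, with mast cell, hemoglobin and chemokine genes among them. These cells may be doublets or cells of another type within the cluster, and which of these holds was not tested.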

How the results depend on the processing

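Of the named genes past 2-fold, only those given here turned. No paired analysis was possible because the values come from no test and no class had 20 cells in both samples. For the same reason the tests on summed counts, with other size factors or with their filter on low counts, the fit with no replicate block and the leaving out of either sample were not run. Set against the highest other class, in place of the mean, the stellate-like class had 26 list genes higher and 271 lower and the endothelial class 12 higher, as this asks more of a higher and less of a lower gene. In the stellate-like cells of replicate 1, a choice made after seeing the data, 52 of 79 higher and 28 of 49 lower list genes stayed, and the cause was not tested. Without a floor on UMIs 857 central and 653 portal genes of stellate-like cells and 688 and 671 of endothelial cells passed 2-fold, since genes with few counts enter. Thinned to 2000 UMIs, with the score remade, 57 central genes of stellate-like cells (39 of them the same) and 52 central and 44 portal genes of endothelial cells (36 and 30) passed, with depth, score and cells all changed, so the cause was not told apart. Random landmarks gave medians of 9 and 8 genes in stellate-like and 14 and 10.5 in endothelial cells. Without the Rasd1 cluster, left out after seeing the data, 73 endothelial portal genes passed, from fewer cells.

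Notch3 turned from a log2 fold of -3.09 to 0.23 at resolution 0.5 and 0.44 at resolution 2, where 9 smooth muscle-like cells joined the stellate-like class and the 18 others, too few, left the comparison; which of the 2 turned it was not told apart. Htra1 turned to 0.16 with the 2 stellate-like clusters in place of the score, and Tagln, within 2-fold, to 0.09. The central genes Ccl4 and Il6 of endothelial cells turned to -0.0693 and -0.41 with doublets kept, -0.35 and -0.67 under the stricter filter, -0.50 and -0.33 at resolution 2 and -0.96 and -0.79 without the Rasd1 cluster. In these cases the cause was not tested, and 5 named endothelial genes had too few counts for a value. Stellate-like cells made up 100% of replicate 2 at resolutions 0.5 and 2 and with all variable genes. The endothelial share was 41.2% at resolution 2 and 39.5% with all variable genes. The Kupffer-like share was 36.0% at resolution 0.5, 27.3% at resolution 2, 35.9% with doublets kept and 36.2% under the stricter filter, and 743, 197, 740 and 565 cells of the Naip1 cluster then carried that name. A gene with a 3-fold change from end to end passed the rule in 18 and 22 of 100 simulated cases, so the rule leaves out most changes of that size.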

Other observations

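The test of shared genes along both axes was written down before its result was seen. The clusters read below were chosen after the data were seen.

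Rspo3, Wnt2 and Wnt9b were higher in the unnamed cluster of 336 cells than in the 3 sinusoidal endothelial-like clusters. It was made without Rspo3, Wnt2, Wnt9b and Bmp4 among its variable genes. Rspo3 stood at 2293 CPM (2224 to 2363) there and at 29.4, 7.72 and 15.7 CPM in the sinusoidal endothelial-like clusters. Wnt9b stood at 244 CPM (222 to 268) against 11.2, 7.29 and 6.74, Wnt2 at 739 (700 to 779) against 386, 310 and 208, and Bmp4 at 84.2 (71.5 to 98.5) against at most 0.429. The Notch ligand Dll4 went the other way, at 36.4 CPM (28.2 to 46.2) against 130, 121 and 139, as did Efnb2 at 35.3 against 155, 143 and 199. All cells were of replicate 1, and the intervals cover counting error only.

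Kupffer-like cells fell into 2 clusters that differed in cytokine genes left out of the clustering. The larger, of 1116 cells, had Cxcl2 at 2193 CPM (2158 to 2229) and Il6 at 802 (780 to 823), and the other, of 548 cells, had 256 and 87.0 CPM. Among sinusoidal endothelial-like clusters, the 681 cells led by Rasd1 had Cxcl10 at 1773 CPM (1737 to 1810) and Cxcl9 at 560 (539 to 581), against at most 483 and 258 CPM in the others. Of the stellate-like clusters, the one with Adamtsl2 and Spon2 among its leading genes had Rspo3 at 1524 CPM (1487 to 1563) and the one with Ngfr and Il34 had 1115 (1091 to 1139), while Cxcl10 stood at 142 and 369 CPM.

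A shared set of genes along the central to portal axis of stellate-like and endothelial cells was put up as a hypothesis, with a Spearman correlation of at least 0.2 predicted. The correlation was 0.0497, so a link of that size was not seen across all 8527 genes. Most of these stayed within 2-fold on both axes, so the value cannot decide whether the genes past 2-fold were shared. Central in both were 3 genes against 0.184 if independent, and portal in both 7 against 0.361, so a small common part may exist, and these counts were not tested.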
